A study of Mus musculus with 8 samples.

How the data were processed

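The study measured gene expression by RNA sequencing in whole eyes of WT mice (Cre-negative) and of mice with a retina-specific deletion of Nr3c1, called cKO here. Per the labels, all mice were male, 12 weeks old and kept in 12 h of light and 12 h of dark, and eyes were taken every 6 h at 4 zeitgeber times, hours counted from lights-on: ZT3, ZT9, ZT15 and ZT21. RNA of 3 mice was pooled in equal amounts for each genotype and time, which gave 8 libraries, 4 per genotype. The tissue and cell type fields of the labels name the ciliary body and its nonpigmented epithelium, whereas the protocols and the series design name whole eyes; the libraries are called whole eyes here.

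The deposited values are raw counts per gene symbol, with no normalization by the authors. The aligner, the counting program, the genome build, the annotation and the strand of the libraries are not given in the sources used here. The table holds 32544 gene symbols. In 27 of them the symbol had been turned into a date by a spreadsheet program, and these were left out because the gene could not be identified for certain; they held 0.123 to 0.145% of the counts of a library. Total counts ran from 11748995 to 20309611 per library. For a share of a library's counts, the 95% binomial confidence interval (Wilson) reached at most 0.0211 percentage points to either side; such intervals cover counting error only and not the differences between mice.

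Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr by genotype, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05), and 15373 genes were tested. Levels are given as CPM, counts scaled to the TMM-adjusted library size. The genotype comparison used time as a factor with 4 levels, which leaves 3 residual degrees of freedom. The rhythm shared by both genotypes was a cosine wave with a period of 24 h on top of the genotype (4 residual degrees of freedom). The rhythm of WT, that of cKO and the difference between them came from a fit with a wave in each genotype (2 residual degrees of freedom). With 4 times, 6 h apart, the wave cannot be told from other shapes of the same phase, so its amplitude and peak time describe a contrast of 4 time points. As no genotype and time has a repeat library, the p-values measure the spread between these 8 pools around each model, not the spread between mice. The labels link a WT pool to a cKO pool only by the time of collection, which entered the genotype comparison as a factor, so that comparison is made within times.

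The tests were checked on simulated counts with the real means, library sizes and dispersions. Each gene was drawn on its own, without time effects other than the simulated change and without shifts shared by a whole library. At a simulated 2-fold change, 76.1% of the changed genes were recovered for the genotype comparison and 10.4% for the common rhythm. At 4-fold, the recovery was 100% and 95.5% for these, 54.5% for the WT rhythm, 72.7% for the cKO rhythm and 3.03% for the difference in rhythm. Of the calls on simulated data, 12 of 142 were false for the genotype and 3 of 73 for the common rhythm, but 14 of 51 for WT, 21 of 72 for cKO and 10 of 12 for the difference in rhythm. Calls from the fits with 2 residual degrees of freedom are therefore less dependable than their adjusted p states. The recovery need not hold in the real libraries, which do differ as a whole. In edgeR, Etnppl had an adjusted p of 0.141 at a log2 fold change of -2.13, and Nr3c1 0.157 at -1.73. A lack of calls is therefore not evidence against changes of 2-fold or 4-fold.

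Before the data were examined, 34 gene lists were fixed. They cover the core clock, the glucocorticoid response, light, dopamine and melatonin signalling, immediate early genes, retinal stress, interferon and antigen presentation, heat shock and temperature, cholesterol synthesis, the mitochondrial genome, the nuclear respiratory chain, glycolysis and housekeeping. They also hold markers of rods, cones, bipolar cells, Müller glia, amacrine cells, horizontal cells, ganglion cells, retinal pigment epithelium, melanocytes, lens, cornea and conjunctiva, ciliary body and aqueous outflow, skeletal muscle, smooth muscle and pericytes, exocrine glands, adipocytes, endothelium, fibroblasts, immune cells, erythrocytes and oligodendrocytes, and a check of sex-linked genes. Members were counted as past the threshold over all genes tested and, beside that, adjusted over the list alone. Lists were also tested with camera (limma 3.58.1, preset correlation 0.01, then a correlation estimated per list) and fry (for 1 direction and, added after the data were seen, for change in either direction), and their mean log2 level was compared between genotypes by a two-sided exact permutation test over the 70 arrangements of 8 libraries. That test cannot give a p below 0.0286.

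The rule for naming genes was fixed at the same time. It takes Nr3c1 first, then the genes past the threshold with the largest change, or the 5 with the smallest p in each direction where none passed, every measured core clock gene, the 5 or 10 genes with the smallest p of each rhythm test, and up to 4 members of each list with the smallest p. Gene models without a name are left out of the first parts. Genes named outside this rule are marked where they appear.

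The alternatives fixed before the data were examined were DESeq2's size factors in edgeR, no filter on low counts, a filter at 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, library sizes without the lens, skeletal muscle and gland lists, the lens list as a covariate, other time terms, each genotype fitted alone, and leaving out each library in turn. Chosen after the data were seen were removal of each library's trend on transcript length and GC content (splines with 4 degrees of freedom), the mitochondrial list as a covariate, fits without both ZT3 or both ZT9 libraries, an amplitude ratio over the 200 genes with the smallest p of the common rhythm, and a count of genes with a range of at least 2-fold over time, at a mean of at least 10 CPM and with a pseudocount of 0.5. Without both libraries of a time, the fit of the common rhythm has 2 residual degrees of freedom. Its wave then takes up any difference between the remaining times, so its calls are not of a 24 h rhythm in particular. Transcript length and GC content came from GENCODE M21 (GRCm38) and were known for 97.2% of the genes tested. Gene positions come from the same annotation, and the build behind the deposited counts is not known. Shares, permutations and figures were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Results for some single genes withheld for evaluation are not reported here, and the counts of named genes and of their alternative fits leave them out.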

Results

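RNA sequencing of whole mouse eyes gave 8 libraries, 4 from WT mice and 4 from cKO mice, in which Nr3c1, the gene of the glucocorticoid receptor, was deleted in the retina. Each genotype has 1 library at ZT3, ZT9, ZT15 and ZT21, each made from the pooled RNA of 3 mice. No value at a single time has a replicate, and the 4 times of a genotype are the replicates of its mean (n = 4 libraries per genotype throughout). Total counts at ZT3, ZT9, ZT15 and ZT21 were 15255578, 11748995, 12342508 and 13610914 in WT and 16510594, 20309611, 13672717 and 16343113 in cKO. The 25 rod genes of the marker list took 6.49 to 7.72% of the counts and the 29 lens genes 14.7 to 24.03%, so the libraries hold the transcripts of several eye tissues beside the retina. The p-values of single genes, of fry and of the exact permutation tests rest on the spread between these 8 pools. Those of camera, of the amplitude ratio and of the differences between lens genes compare genes with each other.

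The first comparison asked which genes differ between WT and cKO eyes at all times. Nr3c1 itself was lower in cKO at 4 of 4 times, with 35.6 ± 2.37 CPM against 120.9 ± 29.5 CPM in WT (mean ± SD, n = 4), which is 29.4% of the WT level. In single libraries it had 78.2, 145.1, 126.7 and 133.7 CPM in WT and 38.2, 35.3, 36.4 and 32.5 CPM in cKO at ZT3, ZT9, ZT15 and ZT21. The log2 fold change was -1.73 (SE 0.18), and the adjusted p in edgeR was 0.157 and that in DESeq2 4.44e-13. A two-sided exact permutation test on the log2 levels gave p = 0.0286, the smallest that 4 against 4 libraries allow. The gene lies on chromosome 18 from 39410545 to 39519421 on the minus strand (GRCm38, GENCODE M21), with 9 exons in its longest annotated transcript. The counts are per gene, so which exons the remaining reads cover was not analysed here.

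Beside Nr3c1, the genes with the smallest p in the direction of lower levels in cKO were Etnppl, Rnf207, Snhg11 and Adam1a. Etnppl, which encodes a phospho-lyase of ethanolamine phosphate found in astroglia, had 2.55 ± 0.37 CPM in cKO and 11.8 ± 4.83 CPM in WT (log2 fold change -2.13, SE 0.19, n = 4). Rnf207 (log2 fold change -0.90, SE 0.10) and Snhg11 (-0.97, SE 0.14) were lower at 4 of 4 times. On the other side were Pdyn, the precursor of the dynorphin opioid peptides, with 13.7 ± 3.58 CPM in cKO and 5.64 ± 2.70 CPM in WT (log2 fold change 1.33, SE 0.17), Schip1 (1.15, SE 0.15), Fxyd6, a regulator of the sodium pump (0.79, SE 0.10), Serpini1, which encodes neuroserpin (0.71, SE 0.11), and the lens transcription factor Hsf4 (0.58, SE 0.09), each higher at 4 of 4 times. Etnppl lies on chromosome 3 from 130617448 to 130637521 and Pdyn on chromosome 2 from 129686565 to 129699844 (GRCm38).

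edgeR called 0 genes past an adjusted p of 0.05 between the genotypes, with a smallest adjusted p of 0.141. At an unadjusted p under 0.05 it counted 3310 of 15373 genes (21.5%), 1620 higher and 1690 lower in cKO. That count ran from 1951 to 3884 on leaving out 1 library and was 1666 with the lens list and 276 with the mitochondrial list as a covariate. DESeq2 called 546 genes, 397 higher and 149 lower, after leaving 6855 genes without an adjusted p, and limma-voom called 0 with 3392 at an unadjusted p under 0.05. Without a filter on low counts edgeR called 7 genes, among them Etnppl, Nr3c1, Pdyn and Rnf207.

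**Figure D1:**
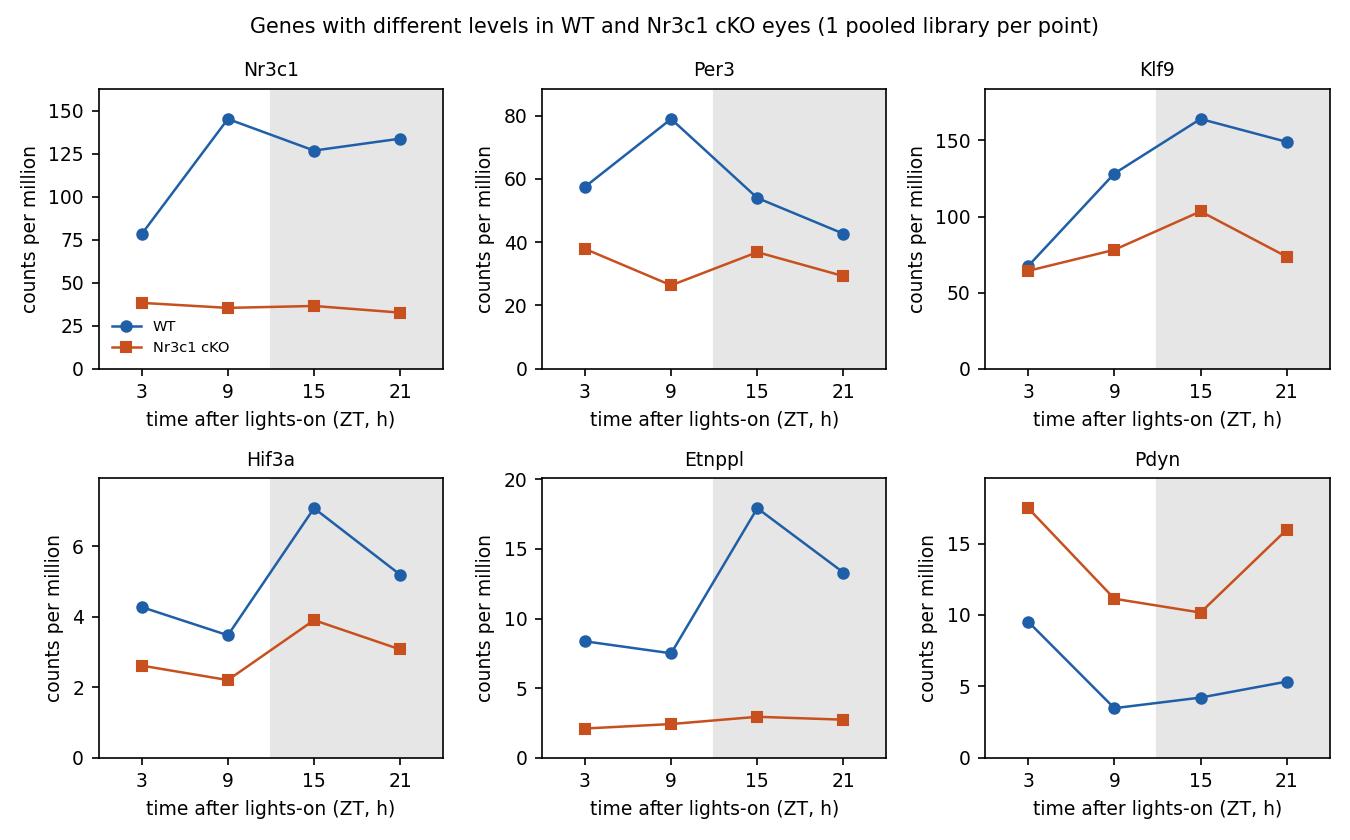
Levels in CPM, counts scaled to library size (vertical axis), of 6 genes at the 4 times after lights-on (horizontal axis, h), with 1 pooled library per point, WT as blue circles, cKO as orange squares and the dark phase in grey. Nr3c1 has 78.2 to 145.1 CPM in WT and 32.5 to 38.2 CPM in cKO, and Per3, Klf9, Hif3a and Etnppl are lower in cKO at 4 of 4 times while Pdyn is higher.

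Of 31 measured genes known to be induced by glucocorticoids, 12 had a positive and the others a negative log2 fold change, with a median of -0.12, and 8 were lower against 5 higher at 4 of 4 times. The list as a whole passed no test for a shift in 1 direction (adjusted p 0.276 in camera and 0.205 in fry, exact permutation p = 0.429 without regard to time), although its mean was lower in cKO at 4 of 4 times. In fry for change in either direction, examined after the data were seen, it was the 1 list of 34 past the threshold (adjusted p 0.0117). Klf9, a transcription factor, had 79.8 ± 16.7 CPM in cKO and 127.3 ± 42.5 CPM in WT (log2 fold change -0.62, SE 0.16, adjusted p in DESeq2 0.0297). Hif3a (-0.75, SE 0.16) and Zbtb16 (-0.58, SE 0.14) were lower at 4 of 4 times, whereas Glul, glutamine synthetase of Müller glia, was higher (0.50, SE 0.16, adjusted p in DESeq2 0.0411). In edgeR 0 members passed over all genes and 0 adjusted over the list alone, with 3 higher and 5 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower.

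Among the clock genes, Per3 had 32.6 ± 5.66 CPM in cKO and 58.3 ± 15.2 CPM in WT (log2 fold change -0.82, SE 0.19, adjusted p in DESeq2 0.0119), lower at 4 of 4 times. Usp2 had a log2 fold change of -0.58 (SE 0.17) and was lower at 3 of 4 times. Of 25 measured core clock genes, 0 passed in edgeR over all genes or adjusted over the list alone, 2 were lower at an unadjusted p under 0.05, and DESeq2 called Per3 alone.

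Transcripts of the mitochondrial genome, of the lens and of Müller glia were, by number and not by share, the groups with the most members higher in cKO past the threshold adjusted over the list alone. All 13 mitochondrial messenger RNAs rose adjusted over the list alone, with a median log2 fold change of 1.2, for example mt-Co3 (1.65, SE 0.37) and mt-Nd6 (0.82, SE 0.14), each higher at 4 of 4 times. These transcripts took 5.49% of the counts at ZT3 and 1.09 to 1.35% at the other times in WT, and 6.12%, 3.69%, 2.08% and 3.63% in cKO. The two-sided exact permutation test gave p = 0.286 for this share and p = 0.114 for the list mean, without regard to time. The 13 transcripts moved together (estimated correlation 0.94), so they are not 13 separate observations. Of the 29 lens genes 18 rose adjusted over the list alone, with a median of 0.58, among them the membrane protein Lim2 (0.75, SE 0.14), Grifin (0.79, SE 0.14) and Lctl (0.76, SE 0.14). The lens list took 21.7 ± 1.99% of the counts in cKO and 16.0 ± 1.60% in WT (two-sided exact permutation p = 0.0286, the smallest possible). For the mean of the lens list, the two-sided exact permutation test gave p = 0.0571. Both lens tests were without regard to time. Of the 20 Müller glia genes 9 rose adjusted over the list alone, among them Abca8a (0.58, SE 0.11), Apoe (0.83, SE 0.20), Clu (0.81, SE 0.21) and the glutamate transporter Slc1a3 (0.63, SE 0.14). The median of this list was 0.29, and 2 members were lower at an unadjusted p under 0.05. The housekeeping list had a median of 0.32 with 7 of 15 genes higher, so the glial shift was no larger than that of housekeeping genes.

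Smaller numbers of other genes rose in the same direction, each adjusted over the list alone. They were 2 of 17 cone genes, the short-wave opsin Opn1sw (0.90, SE 0.18) and Pde6h (0.39, SE 0.10), 3 of 19 ganglion cell genes, Sncg (0.98, SE 0.17), Thy1 (0.69, SE 0.16) and Stmn2 (0.41, SE 0.10), and 5 of 30 genes of the nuclear respiratory chain, with Cox4i1 at 0.63 (SE 0.14) and Ndufa4 at 0.49 (SE 0.12). Of 13 smooth muscle genes 3 rose, among them Myl9 (0.62, SE 0.11) and Myh11 (0.47, SE 0.12), and of 21 genes of the cornea and conjunctiva 2 rose, Krt13 (0.72, SE 0.17) and Lypd2 (0.71, SE 0.16). Of 15 housekeeping genes 7 rose and 1 fell, and examples of the first are the ribosomal genes Rplp0 (0.78, SE 0.15) and Rpl13a (0.61, SE 0.13).

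Of 8 erythrocyte genes 5 fell adjusted over the list alone, with log2 fold changes of -1.60 (SE 0.41) for Hba-a1 and -1.58 (SE 0.39) for Hba-a2, and in WT these genes were highest at ZT15, with 3738 CPM of Hba-a2 against 393 to 812 CPM at the other times. Of 20 immune cell genes 2 rose, among them C1qb (0.86, SE 0.21), and the leukocyte gene Ptprc fell (-1.04, SE 0.21). Of 12 oligodendrocyte genes Mal rose (0.48, SE 0.12) and Mag fell (-1.15, SE 0.29). The 4 measured sex-linked genes, all on the Y chromosome, had negative log2 fold changes, although all mice were male per the labels. Of these, 3 fell adjusted over the list alone, for example Kdm5d (-0.58, SE 0.14), and 1 did so with the trend on length and GC content removed. Xist, the remaining member of that list, was not among the genes tested.

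In 21 lists 0 of 395 members, some counted in more than 1 list, passed in edgeR adjusted over the list alone. These are the clock, glucocorticoid, light and dopamine, immediate early, retinal stress, interferon, heat shock, cholesterol, glycolysis, rod, bipolar, amacrine, horizontal, pigment epithelium, melanocyte, ciliary body, skeletal muscle, gland, adipocyte, endothelium and fibroblast lists. At an unadjusted p under 0.05 they held 69 higher and 21 lower members, and DESeq2 called 23. Examples are Eno1 (0.47, SE 0.14) and Ldhb (0.48, SE 0.14) of glycolysis, with 10 members higher and 1 lower at an unadjusted p under 0.05, H2-K1 (0.58, SE 0.15) of antigen presentation, and C1ql2 (0.51, SE 0.12) of amacrine cells. Over all genes tested, every one of the 34 lists had 0 members past the threshold in edgeR.

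Camera with its preset correlation called 19 of 34 lists, 17 higher and 2 lower in cKO, led by the lens (adjusted p = 5.71e-14) and mitochondrial lists. None held with an estimated correlation, the smallest being adjusted p = 0.52 with an estimated correlation, and fry for 1 direction called 0 with a smallest adjusted p of 0.205. In the exact permutation test of list means, 2 lists reached p = 0.0286, smooth muscle and the sex-linked genes, both with an adjusted p of 0.259. Without both ZT9 libraries 13 mitochondrial and 14 lens genes were past the threshold, beside 3 of housekeeping, 1 each of Müller glia, ganglion cells, smooth muscle and the sex-linked genes, and 0 of the cone, nuclear respiratory, cornea, erythrocyte, immune and oligodendrocyte lists. Without both ZT3 libraries 13 mitochondrial, 8 lens, 10 Müller glia and 0 nuclear respiratory genes were higher and 2 Müller glia genes lower, beside 16 of the cornea and conjunctiva list and 9 immune genes. Of lists with 0 members past the threshold in the full data, the ciliary body list then had 6 higher, the melanocyte list 6 with 1 lower, the fibroblast list 5 with 1 lower, the pigment epithelium list 4 with 3 lower, and the cholesterol and amacrine lists 3 each. The retinal stress list had 2 higher, the gland list 2 with 1 lower, the glycolysis and adipocyte lists 1 higher and 1 lower each, the glucocorticoid list 2 lower and the core clock list 1 lower. The core clock list had 1 lower without both ZT9 libraries and with the trend on length and GC content removed as well. Removing that trend gave 13 mitochondrial, 13 lens, 9 Müller glia and 1 nuclear respiratory gene higher and 0 of the cornea and immune lists. It also gave 3 melanocyte genes higher, and 1 glucocorticoid response gene higher and 5 lower. All 3 of these alternatives were chosen after the data were seen.

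**Figure D2:**
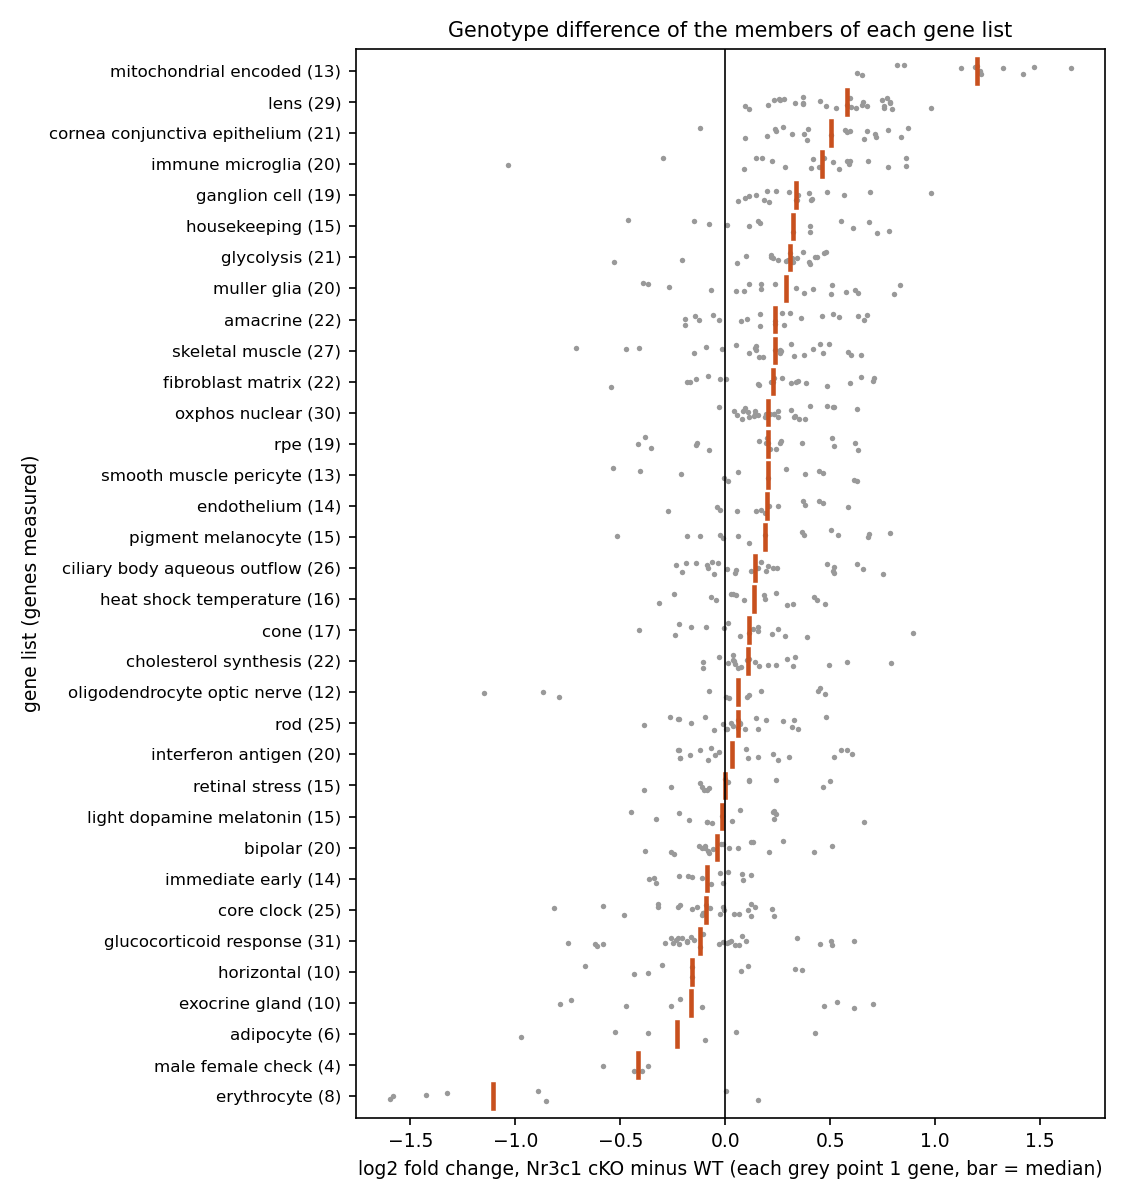
Log2 fold change between cKO and WT (horizontal axis) of each measured gene (grey points) in 34 gene lists (vertical axis, number of genes in parentheses), with the median of each list as an orange bar. The mitochondrial list has the highest median, 1.2, followed by the lens list at 0.58, and the erythrocyte list has the lowest, -1.11.

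The next comparison asked which genes follow the day in both genotypes. Drd4, the dopamine receptor of photoreceptors, peaked late in the night at 502 CPM in WT and 337 CPM in cKO at ZT21, against 68.9 and 101 CPM at ZT3, a fitted peak-to-trough fold of 5.61 (light minus dark -1.75 log2, SE 0.27, n = 8 libraries, adjusted p in edgeR 0.262 and in DESeq2 8.77e-07). Of 14 immediate early genes 6 changed adjusted over the list alone, all higher in the dark, with peak-to-trough folds of 4.46 for Nr4a1, 4.48 for Egr1, 2.35 for Fos, 1.94 for Ier2 and 2.36 for Klf4. Of 15 genes of light, dopamine and melatonin signalling 4 changed adjusted over the list alone: Drd4, Nr4a1 and Fos in the dark, the last pair being also in the immediate early list, and Adcy1, an adenylyl cyclase, around ZT9 (fold 2.06).

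Of 25 core clock genes, Npas2, Dbp and Nfil3 changed adjusted over the list alone. Npas2 peaked at ZT3 with 6.66 CPM in WT and 4.02 CPM in cKO (peak-to-trough fold 5.37), Dbp around ZT11 (fold 1.84) with 166 CPM in WT and 185 CPM in cKO at ZT9, and Nfil3 in the night (fold 2.02). Over the 25 genes the fold ran from 1.05 to 5.37, and 14 stayed under 1.5, among them Arntl (1.19), Per1 (1.37), Per2 (1.13), Cry1 (1.22) and Nr1d1 (1.14). Clock had 335 CPM in WT at ZT9 against 114 to 135 CPM at the other WT times and 103 to 140 CPM in cKO. Without both ZT3 libraries 0 clock genes passed and without both ZT9 libraries 5 did.

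In other groups, Irf7, a transcription factor of the interferon response, peaked at ZT21 in both genotypes (fold 5.87, light minus dark -1.57 log2, SE 0.16, adjusted p in DESeq2 1.79e-13), and with Ifit1 (fold 2.89) it made up the 2 of 20 interferon genes that changed adjusted over the list alone. The lactate transporter Slc16a3 (fold 3.58, 1 of 21 glycolysis genes), the muscle myosin Myh1 (fold 2.84, 1 of 27 skeletal muscle genes), the epithelial keratin Krt15 (fold 2.02, 1 of 21) and Sult1a1 (fold 2.23, 1 of 31 glucocorticoid response genes) were higher in the dark. The cold-inducible RNA-binding protein gene Cirbp (fold 2.61, 1 of 16) was higher in the light. Of 26 genes of the ciliary body and aqueous outflow 7 changed, among them the water channel Aqp1 (fold 2.16, night), the carbonic anhydrase Car3 (fold 3.21, around lights-off), Angptl7 (fold 6.13, night) and Ltbp2 (fold 2.68, morning). Car3 and Lpl were the 2 of 6 adipocyte genes, and of 17 cone genes Opn1sw (fold 2.86, morning) and Arr3 (fold 1.75, night) changed.

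The mitochondrial transcripts (13 of 13, for example mt-Co2 with a fold of 3.27), 4 of 22 cholesterol synthesis genes, for example Insig1 (fold 4.02), peaked near ZT3 adjusted over the list alone, and 6 of 8 erythrocyte genes peaked at ZT15, for example Hba-a2 (fold 4.60). Without both ZT3 libraries 0 of these 3 groups passed, 7 immediate early and 4 light and dopamine genes did, and 2 of the ciliary body list. The interferon, glycolysis and adipocyte lists then had 1 each, and the cone, heat shock, cornea, skeletal muscle and glucocorticoid lists 0. With the trend on length and GC content removed 1 erythrocyte, 1 cone, 2 cholesterol and 3 light and dopamine genes passed, and 0 of the glucocorticoid and cornea lists. The glycolysis list then had 4 and the ciliary body list 11. In the other 19 lists 0 of 334 members passed in edgeR adjusted over the list alone, with 94 at an unadjusted p under 0.05 and 23 called by DESeq2. These are the retinal stress, nuclear respiratory, rod, bipolar, Müller glia, amacrine, horizontal, ganglion cell, pigment epithelium, melanocyte, lens, smooth muscle, gland, endothelium, fibroblast, immune, oligodendrocyte, housekeeping and sex-linked lists. Without both ZT9 libraries many of these had members past the threshold, among them 19 lens, 12 pigment epithelium, 11 Müller glia, 9 rod, 7 fibroblast, 6 ganglion cell and 5 amacrine genes. That fit takes up any difference between ZT3, ZT15 and ZT21. With the trend removed 4 Müller glia and 3 ganglion cell genes passed.

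Over all genes edgeR called 0 for the common rhythm (smallest adjusted p 0.262), with 2731 at an unadjusted p under 0.05 (17.8%). That count ran from 879 to 3751 on leaving out 1 library and was 594 with the mitochondrial list as a covariate. DESeq2 called 609 and limma-voom 0 with 2802 at an unadjusted p under 0.05. Without both ZT9 libraries edgeR called 1543 genes, of which 501 were among those of DESeq2. Camera called 12 of 34 lists between light and dark, 5 higher in the light and 7 in the dark, and 10 between ZT9 with ZT15 and ZT3 with ZT21, 1 higher and 9 lower. None held with an estimated correlation (smallest adjusted p = 0.788 with an estimated correlation for the first and adjusted p = 0.72 for the second). Fry for change in either direction had 11 lists past the threshold for the first and 1 for the second. Without the ZT9 library of WT, or without that of cKO, 6 lists were called between light and dark, 5 higher and 1 lower in the light in the first case and 1 higher and 5 lower in the second. In none of the lists called by camera did the median, the mean and the test differ in sign; they did so in lists that were not called, for example the bipolar list (genotype median -0.04, mean 0.01).

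**Figure D3:**
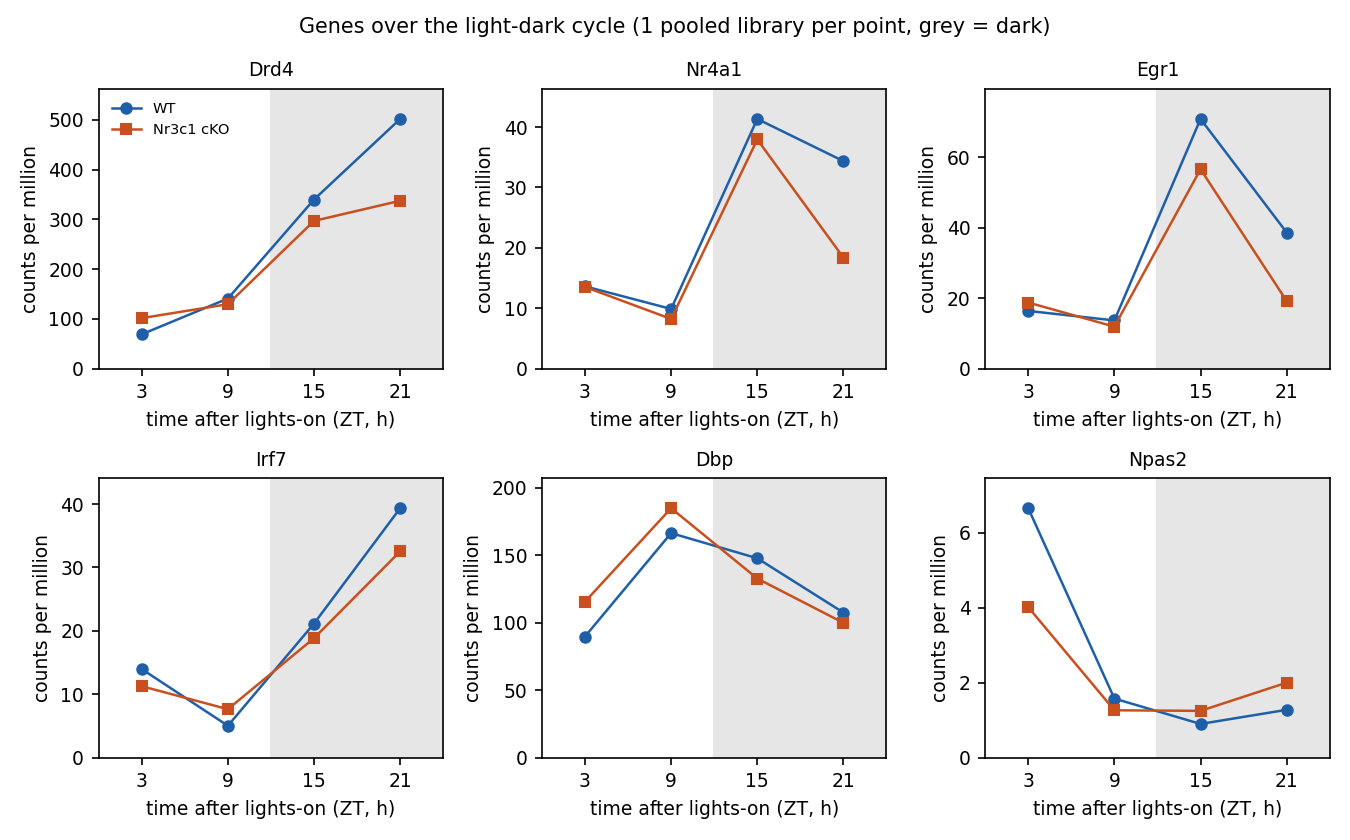
Levels in CPM, counts scaled to library size (vertical axis), of 6 genes at the 4 times after lights-on (horizontal axis, h), with 1 pooled library per point, WT as blue circles, cKO as orange squares and the dark phase in grey. Drd4, Nr4a1, Egr1 and Irf7 are higher in the dark in both genotypes, with Drd4 at 502 CPM in WT and 337 CPM in cKO at ZT21, Dbp is highest at ZT9 and Npas2 at ZT3.

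The study's title asks whether loss of the receptor disturbs rhythmic expression, which the fits with a wave in each genotype address. In WT the genes with the smallest p were Pagr1a, Lmbrd2, Irf7, Zfp26 and Itgb8. Lmbrd2 had 19.9, 59.1, 9.94 and 6.19 CPM over the 4 times in WT and 14.1, 11.4, 10.98 and 14.5 CPM in cKO, a fitted amplitude of 1.72 log2 in WT and 0.25 log2 in cKO. The integrin gene Itgb8 had an amplitude of 1.5 log2 in WT and 0.47 log2 in cKO. In cKO the leading genes were Pagr1a, Tns4, Irf7, Slc16a3 and Car3. Pagr1a had 10.8 CPM at ZT15 in WT and 7.99 CPM at ZT9 in cKO, against 0.31 to 0.83 CPM at ZT3 and ZT21. Tns4 had 8.10 and 9.76 CPM at ZT3 and ZT9 and 32.5 and 27.9 CPM at ZT15 and ZT21 in cKO, and 13.9 to 15.8 CPM in WT.

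The test of the difference in rhythm had its smallest p for Lmbrd2, Vcan, Itgb8, Tns4, Mdm4, Acap2, Nf1, Srp54a, Zfp26 and Slc5a3. In 9 of these 10 genes, all but Srp54a, the WT level was highest at ZT9, though for Tns4 it spanned only 13.9 to 15.8 CPM. Examples are 180 CPM of Mdm4, an inhibitor of p53, against 23.2 CPM in cKO at that time, and 198 against 51.6 CPM of Nf1. Srp54a had 78.8 CPM in WT and 5.14 CPM in cKO at ZT21. The WT library at ZT9 also stood apart as a whole: its deviations ran with transcript length (Spearman's rho 0.29 across genes) and against GC content (-0.40). With these trends removed the genes at an unadjusted p under 0.05 for the difference numbered 289 in place of 474. The 474 are 3.08% of the genes tested, less than the share of 0.05 due without any change. Of the members of the 34 lists, Itgb8 in the pigment epithelium list was the 1 that passed adjusted over the list alone; in the other 33 lists 0 passed in edgeR, with 12 at an unadjusted p under 0.05. No glucocorticoid response, core clock or immediate early gene had an unadjusted p under 0.05 for the difference (0 in each list).

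edgeR called 0 genes in WT (1520 at an unadjusted p under 0.05, 9.89%), 0 in cKO (133, 0.87%) and 0 for the difference (474, 3.08%). The smallest adjusted p were 0.346, 0.9996 and 0.9999. Without any change and with exact p-values, a share of 0.05 would be due, and the shares for cKO and the difference lay below it. The ratio of amplitudes planned over genes called in the common rhythm has no value, as 0 were called there. DESeq2 called 392 in WT, 3 in cKO, namely Angptl7, Pagr1a and Tns4, and 110 for the difference, and limma-voom called 0 in each with 1556, 126 and 484 at an unadjusted p under 0.05. The larger number in WT than in cKO is not a tested difference, and on simulated data 10 of 12 calls for the difference were false. The order also turned around when each genotype was fitted alone, on its own spread. edgeR then called 0 genes in WT (1049 at an unadjusted p under 0.05) and 456 in cKO (2197), so the order depends on the shared estimate of the spread. Leaving out 1 WT library leaves the spread to cKO alone: the WT count then ran from 980 to 4905, the cKO count from 288 to 391 and the difference from 488 to 1442, while leaving out 1 cKO library gave 1 or 2 genes in WT, 0 in cKO and 0 or 1 for the difference.

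**Figure D4:**
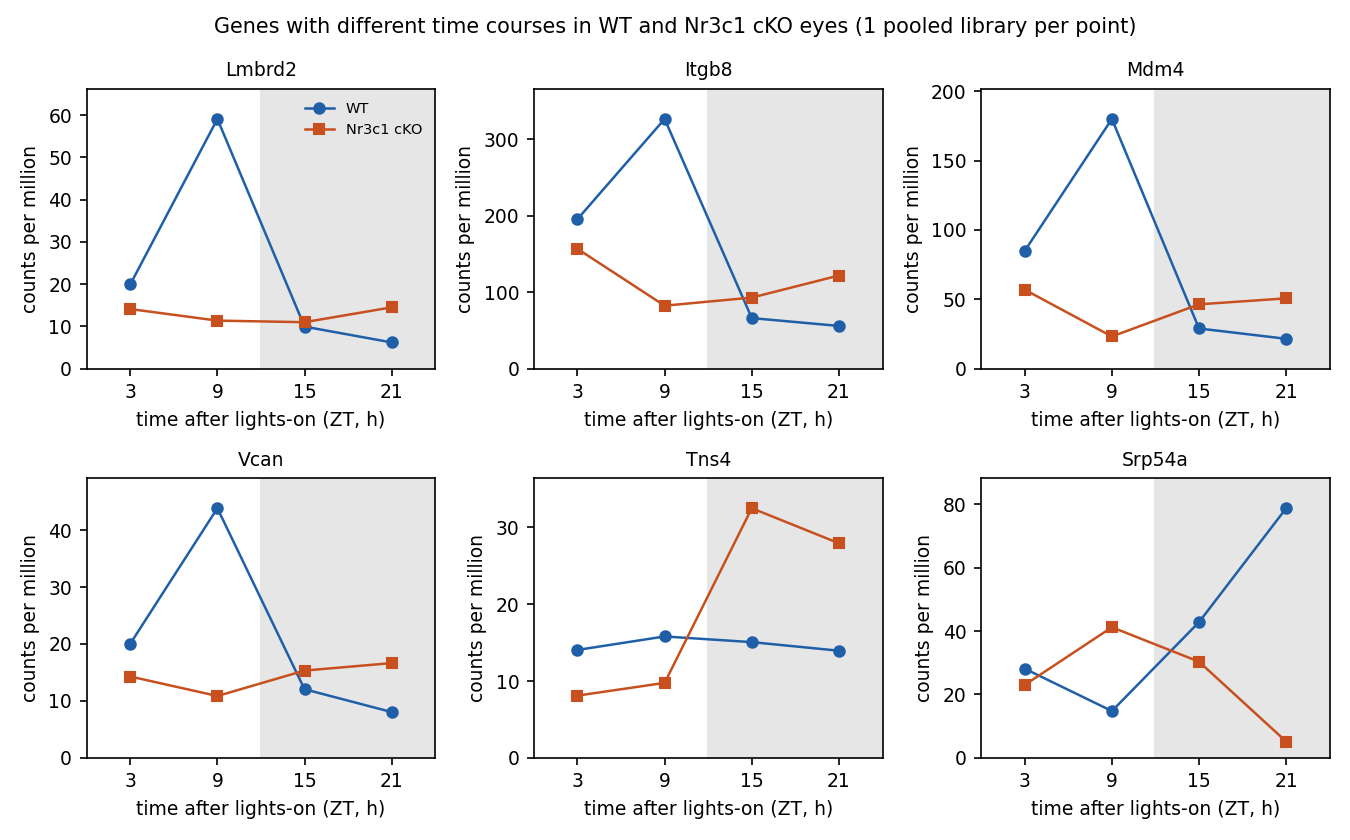
Levels in CPM, counts scaled to library size (vertical axis), of 6 genes with the smallest p for the difference in rhythm, at the 4 times after lights-on (horizontal axis, h), with 1 pooled library per point, WT as blue circles, cKO as orange squares and the dark phase in grey. Lmbrd2, Itgb8, Mdm4 and Vcan are highest in the WT library at ZT9, where Lmbrd2 has 59.1 CPM in WT and 11.4 CPM in cKO.

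Whole libraries also differed. In a principal component analysis of log2 CPM the first component held 52.5% of the variance and set the ZT3 libraries (-51.4 in WT and -43.3 in cKO) apart from the other WT libraries (29.5 to 38.5) with the other cKO libraries between them (-7.36 to 9.05), and the second (24.6%) set apart WT at ZT9 (-47.3). Lars2, the mitochondrial leucyl-tRNA synthetase, had 297 CPM at ZT3 and 5729 to 6568 CPM at the other times in WT, and 605 and 2750 to 4680 CPM in cKO. Lars2 was chosen after its values were seen. Spearman's rho of library deviations with transcript length, across genes, which are not independent replicates, was 0.31 in WT at ZT3, 0.29 in WT at ZT9 and -0.39 in cKO at ZT9. Genes with a range of at least 2-fold over the 4 times, among 10265 with a mean of at least 10 CPM, numbered 2388 in WT and 514 in cKO.

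**Figure D5:**
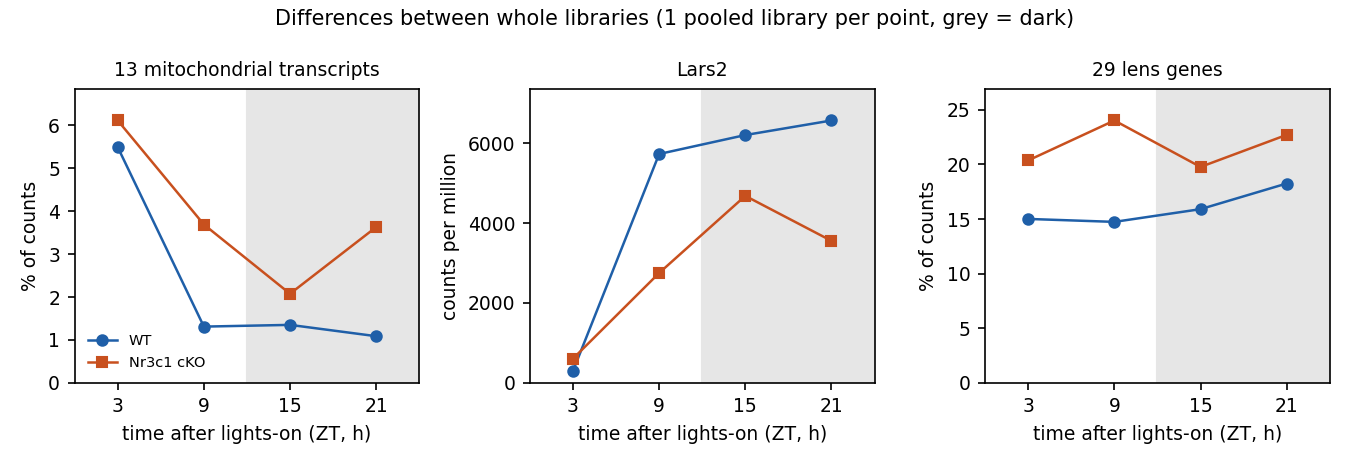
Share of counts of 13 mitochondrial transcripts (left, %), level of Lars2 (middle, CPM) and share of counts of 29 lens genes (right, %) at the 4 times after lights-on (horizontal axes, h), with 1 pooled library per point, WT as blue circles, cKO as orange squares and the dark phase in grey. The mitochondrial share is 5.49% in WT and 6.12% in cKO at ZT3, where Lars2 is lowest in both genotypes.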

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

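In this part, the test of transcripts named for library structure and that of the nuclear respiratory chain between genotypes were tests chosen after the result was seen; that of the nuclear respiratory chain at ZT3 was fixed before. Within each genotype, a library was singled out when its gap to the nearest of the other 3 was a large share of the range of the 4, which chance does in about 1 of 20 groups. This held for 35 of 304 groups tested (5 library measures and the named genes in each genotype, 15.2 by chance), and 24 of the 35 were the ZT3 library of WT. The named genes were picked largely for small p, so more such gaps than in unselected genes come with the selection, and the excess over chance is not a test. As the 4 libraries are 4 times of day, such a gap can be a time of day as much as a property of the library.

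The ZT3 library of WT was the highest for the mitochondrial share of counts (5.49% against 1.09 to 1.35%, gap over range 0.94), mt-Nd6 (0.949), mt-Nd4l (0.973), mt-Co3 (0.942) and mt-Co2 (0.847). The same held for the glial and immune genes Apoe (0.866), Clu (0.901), Slc1a3 (0.951), Lyz2 (0.909) and B2m (0.87), and for Opn1sw (0.881), Thy1 (0.831), Pmel (0.87), Emcn (0.866), Ltbp2 (0.881), Fbln1 (0.982) and the lens gene Crybb2 (0.959). It held also for Insig1 (0.934), Cirbp (0.886), Actb (0.929), Rnf207 (0.868), Snhg11 (0.858) and the clock genes Npas2 (0.882) and Cry1 (0.962). The ZT9 library of WT was highest for Clock (0.906). The ZT15 library of WT was highest for the haemoglobin genes Hba-a1 (0.865), Hba-a2 (0.875) and Hbb-bs (0.908).

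In cKO, the ZT3 library was highest for Pde6h (0.869) and Nr1d2 (0.942). The ZT15 library of cKO was highest for Zbtb16 (0.898) and Egr1 (0.837) and lowest for Pcp2 (0.842), Casq1 (0.838) and Myl9 (0.917). The symbols that had been turned into dates, which no comparison used, held 154626 counts over the 8 libraries.

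Mitochondrial transcripts were higher at ZT3 in both genotypes, by a median of 1.47 log2 over 13 transcripts, and higher in cKO at 4 of 4 times. A higher content of mitochondria would raise the nuclear genes of the respiratory chain with them if their messenger RNA follows that content, which was not tested. At ZT3 the 30 nuclear genes had a median of -0.26 log2 (bootstrap 95% bounds over genes -0.41 and -0.09). In cKO 29 of the 30 were higher, with a median of 0.20 log2 against 1.2 for the mitochondrial list. The bounds over genes there were 0.14 and 0.28, under the 0.30 set for this test. In these libraries the nuclear genes thus did not rise at ZT3, and in cKO they rose by less than the mitochondrial transcripts. Under that condition this goes against a higher content as the whole cause. The bounds resample genes, which move together (estimated correlation 0.75 between genotypes), and leave out the spread between pools. They therefore do not exclude such a content. Another candidate is a difference in how RNA was captured or reads were counted. Lars2, Gm15662 and Gm20594 were 11.1-fold, 11.3-fold and 3.75-fold lower at ZT3 and lower in cKO in 3 of 3 pairs at the other times, but at ZT3 they were higher in cKO, for example Lars2 with 605 against 297 CPM, so they do not mirror the mitochondrial transcripts throughout; Gm20594 shares 42 of its 419 stretches of 31 bases with the mitochondrial ribosomal RNA mt-Rnr2. The smallest fold, 3.75, stays below the 4-fold set for this test and these transcripts were picked on the same libraries, so capture and a change in the mitochondrial transcripts themselves cannot be told apart without reads or repeat libraries.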

How the results depend on the processing

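Chosen after the results were seen were the fits without both ZT3 or both ZT9 libraries, the mitochondrial list as a covariate, the removal of length and GC trends, the amplitude ratio of 200 leading genes, and every alternative for gene lists other than the estimated correlation; the remaining alternatives were fixed before the data were examined. For the genotype difference, with 0 genes as reported, edgeR without a filter on low counts called 7 genes and DESeq2 546, and the other alternatives gave 0. For the common rhythm, also 0 as reported, the values were 3 without a filter, 609 with DESeq2, 1543 without both ZT9 libraries and 0 to 1 on leaving out 1 library (1 without the ZT9 library of cKO). The WT rhythm gave 42 without a filter, 392 with DESeq2, 1301 with the mitochondrial covariate and 1 to 4905 on leaving out 1 library. A fit on WT alone gave 0. The cKO rhythm gave 3 with DESeq2, 456 in a fit on cKO alone, 151 with the mitochondrial covariate and 0 to 391. The difference in rhythm gave 110 with DESeq2, 814 with the mitochondrial covariate and 0 to 1442. With the covariate, or with 1 library of either genotype left out, 1 residual degree of freedom remains in these fits; without 1 cKO library they gave 0 to 2 genes, and the cause of the changes was not tested. Fits of WT, cKO and their difference without both ZT3 or ZT9 libraries leave no residual degrees of freedom and were not run, and the planned amplitude ratio had no genes to use. Nr3c1 passed the threshold without a filter (-1.71, adjusted p 0.00612) and with DESeq2 (-1.72, adjusted p 4.44e-13), did not pass with the other alternatives, whose adjusted p ran up to 0.9999 with the mitochondrial covariate (log2 fold change -1.12), and was lower in cKO in all of them. With an estimated correlation 0 lists were called for the genotype, 0 for light against dark and 0 for ZT9 with ZT15 against ZT3 with ZT21; leaving out 1 library gave 16 to 20, 6 to 14 and 10 to 14 lists. The amplitude ratio of the leading genes, -0.35 as reported, was 0.043 without the ZT3 library of WT and -0.048 without the ZT15 library of cKO, within a range of -0.88 to 0.043. Of 1672 alternative values for 80 genes named for the genotype difference, 1611 kept direction and side of the threshold, 55 passed the threshold in the same direction and 6 turned: C4b -0.018, Rgr -0.024, Pmel -0.039 and Fbln1 -0.17 with the mitochondrial covariate, Rcvrn -0.14 and Amy1 0.42 with the lens covariate. For the genotype difference, leaving out either library of a time, or both, gives nearly the same fit, since the time factor takes up a library left alone. Those alternatives are therefore not separate checks. Of 1340 values for 64 genes of the common rhythm, 1251 were kept, 71 passed and 18, of 11 genes, moved their peak by over 6 h; their amplitudes were, with the mitochondrial covariate, Per1 0.16, Cry1 0.030, Rora 0.45, Rorb 0.060, Tef 0.14, Hlf 0.032, Ciart 0.34, Csnk1e 0.080 and Actb 0.065, without both ZT3 libraries Per1 0.20, Rora 0.29, Tef 0.15 and Ciart 0.10, and without both ZT9 libraries Clock 0.026 and Bhlhe41 0.12. On leaving out 1 library the amplitude ran from 0.15 to 0.56 for Clock (turned without the ZT9 library of WT), from 0.026 to 0.082 for Bhlhe41 (without the ZT15 library of WT) and from 0.023 to 0.45 for Ciart (without the ZT3 library of WT). The cause of these turns was not tested.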

Other observations

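In this part, the fits without ZT3, the differences between lens genes, the amplitude ratio and the count of distinct fits among splits were tests chosen after the results were seen. The range count and the removal of length and GC trends were also added after the data were seen, with the bounds for their tests set before these were run, and the other tests were fixed before. In edgeR 0 genes passed for the common rhythm over all genes, and the folds here are given beside that. The rod arrestin gene Sag had a peak-to-trough fold of 2.21 with its peak near lights-off (adjusted p in DESeq2 0.0222). The calcium sensor Rcvrn had a fold of 1.75 with its peak late in the night but was called by neither edgeR nor DESeq2. In edgeR 0 of 25 rod genes passed adjusted over the list alone, with 6 at an unadjusted p under 0.05, and DESeq2 called 2, while without both ZT9 libraries 9 passed. The bipolar gene Car8 had 54.6 CPM in WT and 54.2 CPM in cKO at ZT9 against 34.5 and 34.7 CPM at ZT21. The neuropeptide Npy of amacrine cells was lowest at ZT21 in both genotypes (fold 2.23). The water channel Aqp4 of Müller glia was highest at ZT3 (fold 1.91).

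Among genes of metabolism and stress, Ldha, the lactate dehydrogenase gene, was higher in the dark in both genotypes (fold 1.81, adjusted p in DESeq2 0.0105), like the lactate transporter Slc16a3. The chaperone gene Hsp90aa1 was also higher in the dark (fold 2.03, adjusted p in DESeq2 0.0167). Of the glucocorticoid response genes, Klf9 had a fold of 1.95 and Fkbp5 of 1.79, with peaks in the early night. The difference in rhythm between genotypes had 0 members of that list at an unadjusted p under 0.05. Over the 200 genes with the smallest p of the common rhythm, the amplitude in cKO was lower than in WT in 159, with a median log2 ratio of -0.35 (sign-flip permutation p = 0.0001 across genes, the smallest possible with 10000 flips, and genes are not independent). In 10 simulations with the same wave in both genotypes the ratio ran from -0.06 to 0.05. The simulated genes varied independently, without shifts shared by a whole library, so this range leaves out that source of spread and cannot judge the ratio. The ratio rests on single libraries, since it was 0.043 without the ZT3 library of WT and -0.048 without the ZT15 library of cKO.

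More genes had a 2-fold range over time in WT than in cKO, 2388 against 514 of 10265. A trend on transcript length and GC content as the whole cause is argued against by the ratio of 4.52 that stayed with the trends removed, and the ZT3 libraries as the whole cause by the ratio of 7.15 without them, though the counts then fell to 701 in WT and 98 in cKO. One hypothesis is that loss of the receptor flattens its target genes. The 17 measured glucocorticoid response genes in this count had a median difference in range of 0.19 log2, at percentile 28.9 of 10000 lists of matched expression (median 0.22), so they showed no sign of flattening more than others, but the bootstrap bound of 0.56 leaves room for it. As each point is 1 pool, differences between pools and an effect of genotype cannot be told apart for this count.

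Lens genes were higher in cKO, with log2 fold changes from 0.10 to 0.98 over 29 genes. A larger share of lens in the cKO pools would raise them alike if the lens had the same make-up and they were expressed there alone. Their differences were larger than the spread over times (permutation p = 0.0001, the smallest possible with 10000 permutations). They ran from Foxe3 at 0.10 (SE 0.15) to Cryaa at 0.98 (SE 0.26), 2 genes chosen after their values were seen. Those conditions were not tested, and the permutation was run without removing the trends on length and GC content. It therefore does not decide whether lens share is the whole cause or a part of it. A trend on length and GC content as the whole cause is argued against by the median of 0.36 that stayed with the trends removed, against 0.58 before. As the deletion was in the retina and the eyes were whole, how much lens each pool held remains open, and no biological explanation was tested.

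Other splits of the 8 libraries show how far the genotype and time labels stand out. With time as a factor, 3 of the 32 genotype splits that could be fitted gave at least 3310 genes at an unadjusted p under 0.05. The highest other count was 3987. The 2 splits with 3987 are the same fit once time is a factor. That fit compares cKO with WT at ZT9 and ZT21 alone, so it holds part of the genotype difference. Among distinct fits 2 of 20 gave at least 3310. Chance was therefore not excluded, but these splits cannot decide between chance and genotype. Of the 8 swaps of genotype within times, which keep the pairing of the model, the real labels gave the most, with 2049 as the highest other, and 8 swaps are too few for a share under 0.05. Without a time term 7 of 35 splits gave at least the real 1905, and chance could not be excluded. The highest other split there set both ZT3 libraries with the ZT9 and ZT21 libraries of cKO against the rest. It gave 5133 and called 2393 genes past the adjusted threshold. This split differs from the genotype labels only in the ZT3 library of WT and the ZT15 library of cKO. It therefore mixes genotype with ZT3, and its count cannot be assigned to either. For the common rhythm 6 of 72 arrangements of the times gave at least 2731 genes, with 4317 as the highest other, so chance could not be excluded. For the difference in rhythm 5 of 8 swaps of genotype within times gave at least 474 genes, with 1456 as the highest other and 729 as the median of the others. The real labels therefore did not stand out in this count. These swaps are also too few for a share under 0.05.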
